A study of Mus musculus with 6 samples.

How the data were processed

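Lung cells of Miwi2-tdTomato mice were compared. In these animals the fluorescent protein tdTomato reports the gene Piwil4, which encodes the Piwi family protein MIWI2. Per the labels' protocols, C57BL/6 lungs were digested to single cells and sorted without CD45, the surface marker of leukocytes, and with EpCAM, an epithelial surface marker, into tdTomato-negative and tdTomato-positive fractions. Total RNA was then extracted with Trizol, cleaned on columns, amplified with the Ovation RNA-Seq System V2 and made into TruSeq Nano libraries. Both fractions came from each of 3 mice, which gave 6 libraries. The labels call both fractions multiciliated cells. No gate for cilia is given in the sources used here.

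The deposited values are raw read counts per gene symbol, 1 library per file. The submitters' processing notes name FastQC, cutadapt 1.7.1, STAR 2.4.2a, HTSeq and DESeq2, and the builds GRCm38.p4 and mm10. Neither the HTSeq version nor its strand setting is given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Reads aligned to several places have their own summary row, so reads that match paralogs such as Lyz1 and Lyz2 alike may be missing from both. Each file held 48577 genes, among them a row for tdTomato, and 5 HTSeq summary rows. The summary rows were left out of library sizes and tests. Reads in no annotated gene were 45.8% ± 4.31 of all counted rows in the negative libraries and 45.9% ± 3.05 in the positive ones (SD, n = 3 each). Reads that HTSeq could not give to 1 gene were 1.44% ± 0.220 and 1.94% ± 0.0476, and reads aligned to several places were 10.2% ± 0.549 and 10.3% ± 1.91.

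Counts assigned to genes ranged from 5330584 to 6326395 per library. A gene with no read in a library could be at up to 0.475 to 0.585 CPM there (counts scaled by library size), the level of 3 counts. These floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

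From the deposited counts, CPM values with TMM factors, log2 fold changes (tdTomato-positive over tdTomato-negative), standard errors and p-values were computed with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with robust dispersion estimates. The filter filterByExpr, with its count minimum of 10, kept 13175 genes. Benjamini-Hochberg adjusted p-values under 0.05 over these genes were called. A fold against a group with no reads is given as a lower bound, against the mean floor of 3 counts per library in that group.

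The main model had no term for the mouse. The labels give the same individual for the negative and positive library of each number, so the numbers pair the samples. Across genes, the deviations of the 2 libraries of 1 mouse from their group means correlated at 0.263, 0.254 and 0.346, and those of different mice at -0.213 to -0.096. Deviations within a group sum to 0 for each gene, so positive values within mice make those between mice negative by construction. The latter are not separate evidence of pairing. Because the labels pair the samples, the model with the mouse as a replicate block was computed for each result. Its value is given for genes and lists reported here whose call it changes.

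Before the data were examined, 36 gene lists were fixed, covering cilia, the piRNA pathway, lung cell types, immune, stress and metabolic genes. The 30 lists with at least 5 genes kept were tested with camera (limma 3.58.1), which asks whether list members rank higher or lower than the other genes, at a preset correlation between genes of 0.01. The rule for named genes was also fixed. It took Piwil4; the 10 called genes with the largest rise and the 10 with the largest fall among those with an average log2 CPM of at least 1, a symbol not of the Gm or Rik form and 1 direction in all 3 mice; up to 3 members with the smallest p from each list; and genes that check identity. Of the 10 largest falls, 1 is not reported here. Other genes are named as chosen after their values were seen.

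Alternatives were other normalizations, no filter and a stricter one, DESeq2 1.42.0, limma-voom, the replicate block, a test against a fold of 1.5, an estimated correlation, the fry test, and leaving out each library and each mouse. A correction for GC content and transcript length (mgcv 1.9.3) and a run without mitochondrially encoded genes were added after the data were seen. Gene positions come from GENCODE M21 on GRCm38, which held 12764 of the genes tested. Both models were tested on simulated data over 13175 genes with these libraries' means and sizes. The mouse effect in these data was assumed and the dispersion was set below its estimate, so the shares recovered depend on those settings. The main model recovered 56% of genes made 4-fold different and 0% of those made 2-fold different, with 0% of calls on unchanged genes. The blocked model recovered 83% and 53%, with 5.73% of calls on unchanged genes.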

Results

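RNA was sequenced from sorted mouse lung epithelial cells with and without the tdTomato reporter of Piwil4, to find which transcripts differ between the 2 fractions. There were 3 tdTomato-negative and 3 tdTomato-positive libraries, 1 of each from each of 3 mice. Counts in genes were 5330584, 6326395 and 5432227 in the negative libraries of mice 1, 2 and 3, and 5763317, 5602309 and 5667162 in the positive ones. The positive library of mouse 1 stood apart on the first principal component, which held 37.6% of the variance, at 79.4 against -35.2 to 7.80 for the others. Genes with at least 1 read numbered 21790 ± 569 in the negative and 19470 ± 421 in the positive libraries (SD, n = 3 each), with no overlap between the groups. The exact permutation p was 0.1, the smallest that 3 against 3 allows. Permutations of library measures, here and below, treated the libraries as unpaired. The 10 most abundant genes of each library held 37.3% ± 6.60 of its counts in genes in the negative and 24.2% ± 1.87 in the positive libraries (SD, n = 3 each), also without overlap (exact permutation p = 0.1). Mitochondrial ribosomal RNA, given below, alone held means of 30.8% and 18.6%, so it makes up most of these shares and is not a separate observation.

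Piwil4 and the reporter followed the sort. Piwil4 (chromosome 9, 14696230 to 14740733, GRCm38) was at 44.0, 29.97 and 45.6 CPM in the negative libraries and 101, 95.7 and 111 CPM in the positive libraries of mice 1, 2 and 3. Its log2 fold change was 1.36 ± 0.208 (SE; edgeR adjusted p = 0.012), higher in 3 of 3 mice. The tdTomato row had 0 reads in all 3 negative libraries and 37, 16 and 18 in the positive ones, so it was at least 6.68-fold higher (edgeR adjusted p = 0.0368). Piwil4 RNA was also measured in the negative libraries, at a mean of 39.9 CPM ± 8.62 (SD, n = 3). The Piwil4 call was lost without the negative library of mouse 1 or 2, without the positive library of mouse 3 and without any 1 mouse, with adjusted p up to 0.165. Over all 9 runs that left out 1 library or 1 mouse, its log2 fold change was 1.19 to 1.47.

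Between the fractions, 82 of 13175 genes passed the edgeR threshold, 6 higher and 76 lower in tdTomato-positive cells. All 82 moved in 1 direction in all 3 mice. The 6 higher genes were Piwil4, tdTomato, Ccnd2, Cpn2, Cdr1 and Cldn18. Among the genes that fell were Sftpc and Lyz2, abundant transcripts of alveolar type 2 cells, the surfactant-making cells of the alveolus. With the mouse as a replicate block, 415 genes passed, 179 higher and 236 lower, and all 82 were among them with the same direction. The blocked count was 633 without mouse 1, 380 without mouse 2 and 59 without mouse 3, of which 279, 165 and 13 were higher. Without TMM factors the split was 22 higher and 54 lower, where the median log2 fold change of all genes was 0.286 against 0.029 with them. The count was 34, 42 and 43 without the negative library of mouse 1, 2 or 3, 47 without the positive library of mouse 3, and 22, 30 and 23 without mouse 1, 2 or 3.

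Ccnd2, which encodes the G1 cyclin D2, rose from 32.0 ± 8.36 to 143 ± 54.4 CPM (SD, n = 3 each), a log2 fold change of 2.16 ± 0.291 (SE; edgeR adjusted p = 0.00575). Cldn18, a tight junction claudin (chromosome 9, 99689461 to 99717267), rose from 244 ± 62.9 to 661 ± 127 CPM (SD, n = 3 each), or 1.44 ± 0.214 on the log2 scale (SE; edgeR adjusted p = 0.0103). Cdr1 on chromosome X rose 3.12-fold (edgeR adjusted p = 0.00538), with reads of its antisense transcript not separable here. Cpn2, a subunit of carboxypeptidase N, rose 4.74-fold (edgeR adjusted p = 0.0288). Of the 9 runs that left out 1 library or 1 mouse, the call was lost in 9 for tdTomato, 8 for Cpn2, 5 for Cldn18, 3 for Ccnd2 and 2 for Cdr1.

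Among the 10 largest falls by the naming rule were Trp63, Mlc1, Olfr171, Gdnf, Tinag, Ros1, Nrn1, Zfp385b and Itih4, these 9 all low in abundance. Trp63, the basal cell transcription factor p63, had 8.26 CPM ± 3.57 in the negative libraries (SD, n = 3) and no read in the positive ones, so it was at least 17.0-fold lower (edgeR adjusted p = 0.00693). Mlc1, also without a read in the positive libraries, was at least 8.23-fold lower (edgeR adjusted p = 0.0197). Itih4 was at 19.9 ± 3.38 CPM against 0.707 ± 0.614 (SD, n = 3 each). Of the 9 runs that left out 1 library or 1 mouse, the call was lost in 9 for Zfp385b, 8 each for Mlc1, Olfr171, Gdnf and Ros1, 7 for Nrn1, 3 for Tinag and 2 each for Trp63 and Itih4.

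**Figure D1:**
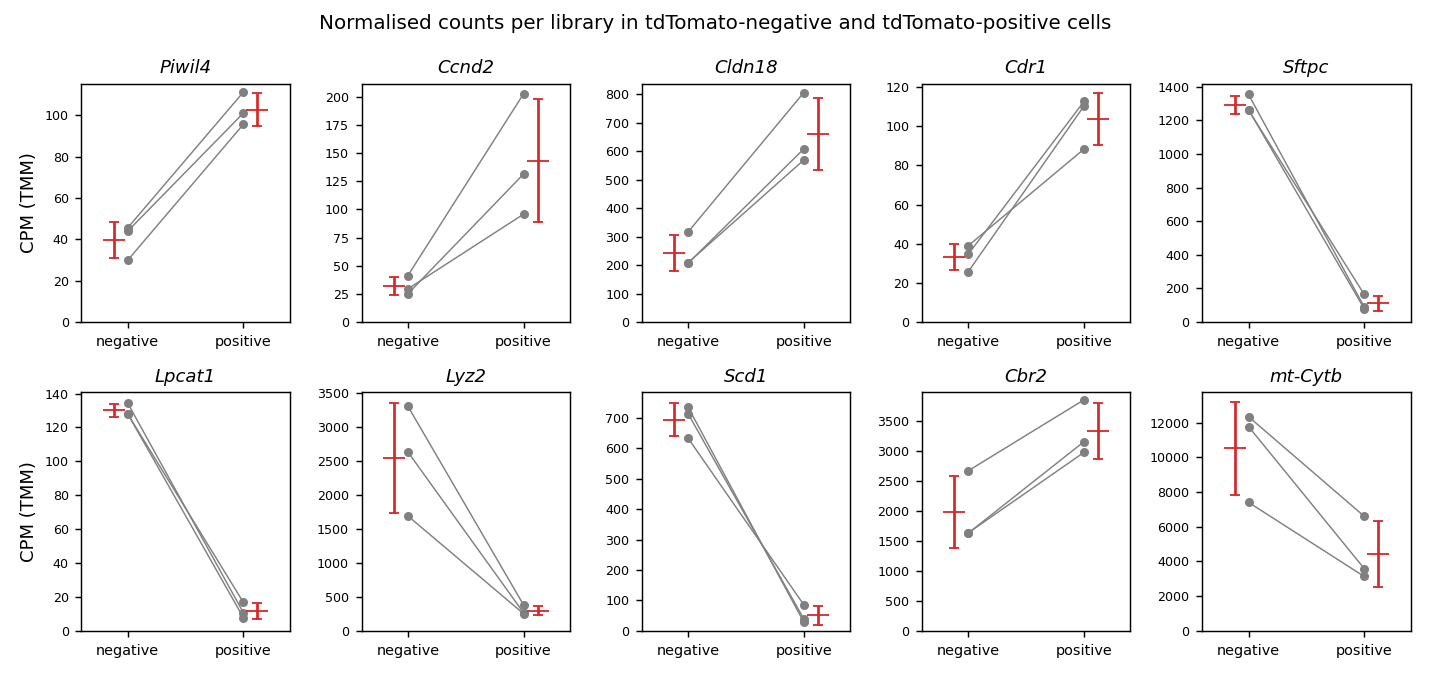
Normalised counts (CPM with TMM factors, linear axis from 0) of 10 genes in each library, with a grey line joining the negative and positive library of each mouse and a red mark for the group mean with its SD (n = 3). Sftpc lies at a mean of 1293 CPM in the negative and 112 CPM in the positive libraries, while Piwil4 lies at 39.9 and 103 CPM; Cbr2 and mt-Cytb did not pass the test without the mouse as a replicate block (edgeR adjusted p = 0.223 and 0.125) and passed with it.

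Of 17 alveolar type 2 markers tested, 9 fell, none rose and 8 were not called; 16 fell when adjusted over the list alone. Sftpc, which encodes surfactant protein C (chromosome 14, 70520949 to 70524081), was at 1264, 1261 and 1354 CPM in the negative and 79.9, 165 and 90.0 CPM in the positive libraries, 11.6-fold lower (edgeR adjusted p = 0.000223). Lpcat1, an enzyme of surfactant lipid synthesis, was 11.1-fold lower (edgeR adjusted p = 0.000223). Lyz2, a lysozyme whose count may lack reads that match Lyz1 as well, was 8.503-fold lower (edgeR adjusted p = 0.000448). The list median was -2.80 on the log2 scale, below 0 in each mouse (-2.81, -2.54 and -3.37), and the list ranked lower (camera adjusted p = 1.66e-71; adjusted p = 0.0375 with an estimated correlation). With the mouse as a block and an estimated correlation, adjusted p was 0.29.

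Fatty acid synthesis genes ranked lower too, with a median of -0.62 over 14 genes (camera adjusted p = 2.66e-06; adjusted p = 0.0772 with an estimated correlation). The main model called only Scd1, a stearoyl-CoA desaturase, at 694 ± 53.6 against 51.1 ± 30.3 CPM (SD, n = 3 each; edgeR adjusted p = 0.00471), and 6 fell when adjusted over the list alone. The Scd1 call was lost without the positive library of mouse 1 (adjusted p = 0.0523) or mouse 1 (0.144). With the replicate block 4 members fell. Fasn, the fatty acid synthase, had a log2 fold change of -1.18 (edgeR adjusted p = 0.0758, and 0.0125 with the block) and Fads2 one of -4.02 (edgeR adjusted p = 0.0774, and 0.0375 with the block); DESeq2 without the block called both (adjusted p = 0.00386 and 0.0433). Fads2 was low, at 2.97 ± 0.828 CPM in the negative and 0.165 ± 0.169 CPM in the positive libraries (SD, n = 3 each). The latter lies below the floor of 3 counts, so the size of its fall is uncertain.

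Club cell markers, genes of the secretory cells of the airway, ranked higher, with a median of 1.37 over 18 genes and 17 above 0 (camera adjusted p = 5.43e-06; adjusted p = 0.493 with an estimated correlation). None was called by the main model, over all genes or adjusted over the list alone. With the replicate block 8 rose, and 12 when adjusted over the list alone. In that fit Cbr2, a carbonyl reductase, had a log2 fold change of 0.78 (edgeR adjusted p = 0.00199), Reg3g, an antimicrobial lectin, one of 2.93 (edgeR adjusted p = 2.22e-05), and Cyp2a5 one of 1.51 (edgeR adjusted p = 0.000289). In the main model their adjusted p was 0.223, 0.256 and 0.289. Without the block Cbr2 was called with no expression filter (adjusted p = 0.000699), Cyp2a5 with no expression filter (0.000102), by DESeq2 (0.00367) and without the positive library of mouse 2 (0.0479), and Reg3g without mouse 3 (0.0474). The list medians in mice 1, 2 and 3 were 1.38, 1.31 and 0.20.

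Mitochondrially encoded mRNAs ranked lower, with a median of -1.15 over 7 genes, each lower in 3 of 3 mice (camera adjusted p = 0.000108; adjusted p = 0.571 with an estimated correlation). None was called by the main model over all genes, and 2 were when adjusted over the list alone; with the replicate block all 7 fell. Without the block mt-Cytb and mt-Co1 were called by DESeq2 (adjusted p = 0.00298 and 0.0295), with no expression filter (1.14e-09 and 1.05e-06) and without the positive library of mouse 1 (0.0143 and 0.0361). In the blocked fit mt-Cytb had a log2 fold change of -1.28 (edgeR adjusted p = 7.22e-05), mt-Co1 one of -1.08 (edgeR adjusted p = 0.000597) and mt-Nd1 one of -1.19 (edgeR adjusted p = 8.08e-05). The list median was -0.653 without the negative and -1.819 without the positive library of mouse 1. The mitochondrial ribosomal RNAs held 30.8% ± 7.48 of counts in genes in the negative and 18.6% ± 1.10 in the positive libraries (SD, n = 3 each), without overlap (exact permutation p = 0.1, the smallest possible). Nuclear-encoded oxidative phosphorylation genes had a median of 0.15 over 30 genes and none was called (camera adjusted p = 0.196). That list passed, as higher, with no expression filter (adjusted p = 0.0107) and without the negative library of mouse 2 (0.0316), the positive library of mouse 2 (0.0167) or mouse 2 (0.001).

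No gene on the ciliary lists was called by the main model, and none of these lists passed in it. Multiciliated cell markers had a median of 0.26 over 19 genes (camera adjusted p = 0.0691, and 0.0039 with the replicate block; 0.674 and 0.59 with an estimated correlation). The medians of that list in mice 1, 2 and 3 were 0.31, -0.17 and 0.38, so mouse 2 did not share the rise. Of its 19 genes, 6 were higher in all 3 mice. Without the block that list also passed, as higher, with library size only (adjusted p = 0.0111), no expression filter (0.00282) or the GC and length correction chosen after seeing the data (0.0176), and without the negative library of mouse 1 (0.0403) or 2 (0.0315), the positive library of mouse 2 (0.00355) or mouse 2 (0.00042). With the block 3 of them rose, Cfap126, Foxj1 and Tppp3, the last 2 chosen after their values were seen. Cfap126 had a blocked log2 fold change of 0.697 (edgeR adjusted p = 0.0301, against 0.289 without the block). Foxj1, the master regulator of motile cilia, had a blocked log2 fold change of 1.20 (edgeR adjusted p = 0.000129, against 0.665 without the block). Axonemal dyneins had a median of 0.09 over 16 genes (camera adjusted p = 0.751), and Dnah12 was at 1994 ± 162 CPM in negative and 1544 ± 36.1 CPM in positive libraries (SD, n = 3 each; edgeR adjusted p = 0.423). Adjusted p from camera was 0.124 for dynein assembly and docking, 0.348 for radial spoke and central apparatus, 0.28 for intraflagellar transport, 0.366 for planar cell polarity and 0.327 for multiciliogenesis regulators. Dynein assembly and docking passed, as higher, with library size only (0.035), no expression filter (0.0107), and without the positive library of mouse 1 (0.0158) or mouse 1 (0.0351). Intraflagellar transport passed with no expression filter (0.0262) and without the positive library of mouse 1 (0.0371), and planar cell polarity with no expression filter (0.0295).

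Of the 24 piRNA pathway genes listed, 5 were kept by the filter. Piwil4 was the 1 called member. Tdrkh, a Tudor protein, had a log2 fold change of -1.29 (edgeR adjusted p = 0.632) and Mybl1 one of -0.79 (edgeR adjusted p = 0.753). The list median was -0.79 and its mean -0.35, while the direction of camera was higher (adjusted p = 0.931).

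Of the markers of other cell types, those of leukocytes ranked lower, with a median of -1.18 over 8 genes (camera adjusted p = 0.0286, and 0.681 with an estimated correlation), and none was called. The leukocyte medians in mice 1, 2 and 3 were -1.39, -1.13 and 0.14, so mouse 3 did not share the fall. Ptprc, which encodes the CD45 used in the gate, had 159, 264 and 25 reads in the negative and 13, 63 and 18 in the positive libraries (edgeR adjusted p = 0.41, and 0.00502 with the replicate block). The leukocyte list lost its call without the negative library of mouse 1 or 2 (adjusted p = 0.0793 and 0.227), the positive library of mouse 3 (0.0781), or mouse 1 or 2 (0.234 and 0.174), and with a stricter filter (0.0553). Its median was -0.479 and -1.835 without the negative library of mouse 2 or 3, -1.902 without the positive library of mouse 2 and -0.579 without mouse 2. Mesenchymal markers had a median of -1.002 over 8 genes (camera adjusted p = 0.087, and 0.00615 with the replicate block; 0.681 and 0.328 with an estimated correlation). Without the block that list passed with library size only (adjusted p = 0.0111) or the GC and length correction (0.0239), and without the positive library of mouse 1 (0.00621) or the negative library of mouse 3 (0.0404). Alveolar type 1 markers went both ways (median 0.05, mean -0.24, camera adjusted p = 0.808): Cldn18 rose, while Ager was 8.72 ± 2.19 CPM in the negative and 1.74 ± 0.406 CPM in the positive libraries (SD, n = 3 each; edgeR adjusted p = 0.0575, and 0.0135 with the replicate block; DESeq2 adjusted p = 0.00548 without it). The camera adjusted p was 0.204 for mesothelial markers, and 0.0136 without the negative library of mouse 3. Fewer than 5 genes were kept of the goblet, basal, neuroendocrine, tuft, endothelial and erythroid lists, which were not tested; Trp63 was the called member of the basal list.

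Of the other lists, 5 passed the preset-correlation test and none did with an estimated correlation. MHC class II genes ranked lower (median -1.79 over 7 genes, camera adjusted p = 0.000437; adjusted p = 0.439 with an estimated correlation), with H2-Ab1 at -1.34 (edgeR adjusted p = 0.191, and 0.00883 with the replicate block). Cell cycle genes ranked lower (median -0.37 over 10 genes, camera adjusted p = 0.0455; adjusted p = 0.439 with an estimated correlation), with Top2a at -2.98 (edgeR adjusted p = 0.0643, and 0.00917 with the replicate block). Immediate early genes ranked higher (median 0.39 over 19 genes, all above 0, camera adjusted p = 0.00261; adjusted p = 0.681 with an estimated correlation), with Zfp36 at 0.61 (edgeR adjusted p = 0.479, and 0.0182 with the replicate block). Xenobiotic and glutathione genes ranked higher (median 0.39 over 23 genes, camera adjusted p = 0.0036; adjusted p = 0.314 with an estimated correlation), and so did Notch pathway genes (median 0.26 over 14 genes, camera adjusted p = 0.00835; adjusted p = 0.492 with an estimated correlation), with Notch1 at 0.77 (edgeR adjusted p = 0.203, and 0.0393 with the replicate block). In these 5 lists no member was called by the main model. Of the members named here, H2-Ab1, Top2a, Zfp36 and Notch1 were called without the block with no expression filter (adjusted p = 0.00287, 0.000693, 0.0317 and 0.0203), H2-Ab1 and Top2a by DESeq2 (0.041 and 0.00199) and Top2a with a stricter filter (0.0449); others of the lists, H2-Aa, Cd74 and Mki67 among them, were called by DESeq2 as well (0.00957, 0.000107 and 0.00894). The immediate early, Notch and cell cycle lists each lost their call without the negative library of mouse 2 (adjusted p = 0.16, 0.09 and 0.09), and also without the positive library of mouse 1 (0.0535) or 3 (0.111) for the first, the positive library of mouse 2 (0.106) or mouse 2 (0.257) for the second, and the positive library of mouse 3 (0.065) or mouse 2 (0.187) for the last. The GC and length correction also ended these 3 calls (camera adjusted p = 0.2, 0.101 and 0.0612), with medians of 0.301, 0.215 and -0.268. With that correction and the replicate block, the immediate early list kept its call. The Notch and cell cycle lists did not (camera adjusted p = 0.0713 and 0.0647). The cell cycle list also lost its call with upper-quartile normalization (camera adjusted p = 0.0615) and without mitochondrially encoded genes (camera adjusted p = 0.0503). Its medians there, -0.439 and -0.38, were no smaller in size than in the main model. Medians moved by over 1.5 times in some runs that left out 1 library or 1 mouse. That of MHC class II was -0.91 without the negative library of mouse 1 and -0.90 without mouse 1. That of the cell cycle list was -0.772 and -0.702 without the negative library of mouse 2 or 3, -0.104 without the positive library of mouse 3 and -0.793 without mouse 2. That of the Notch list was 0.397 and 0.175 without the negative library of mouse 1 or 2 and 0.154 without mouse 2, that of the immediate early list 0.604 without the positive library of mouse 2, and that of the xenobiotic and glutathione list 0.171 without the positive library of mouse 1 and 0.253 without the negative library of mouse 2.

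Epithelial junction genes passed with the replicate block (camera adjusted p = 0.0118, against 0.0561 without it; 0.59 and 0.619 with an estimated correlation). Without the block that list also passed with library size only (adjusted p = 0.0293), with no expression filter (0.00282), without the negative library of mouse 1 or 3 (0.0269 each), without the positive library of mouse 1 (0.0351) or 2 (0.0186), and without mouse 1 (0.0225) or 2 (0.0209). Interferon-stimulated genes (camera adjusted p = 0.931), MHC class I genes (0.931), inflammatory cytokines (0.168), heat shock genes (0.967), the unfolded protein response (0.931), cytosolic ribosomal proteins (0.111) and cholesterol synthesis (0.735) did not pass. Among these, inflammatory cytokines passed, as lower, with no expression filter (0.0146) and without the negative library of mouse 3 (0.000306) or mouse 3 (0.00619), and cytosolic ribosomal proteins, as higher, with no expression filter (0.00351) and without the negative library of mouse 1 (0.0176), the positive library of mouse 2 (0.00011) or mouse 2 (6.37e-05).

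**Figure D2:**
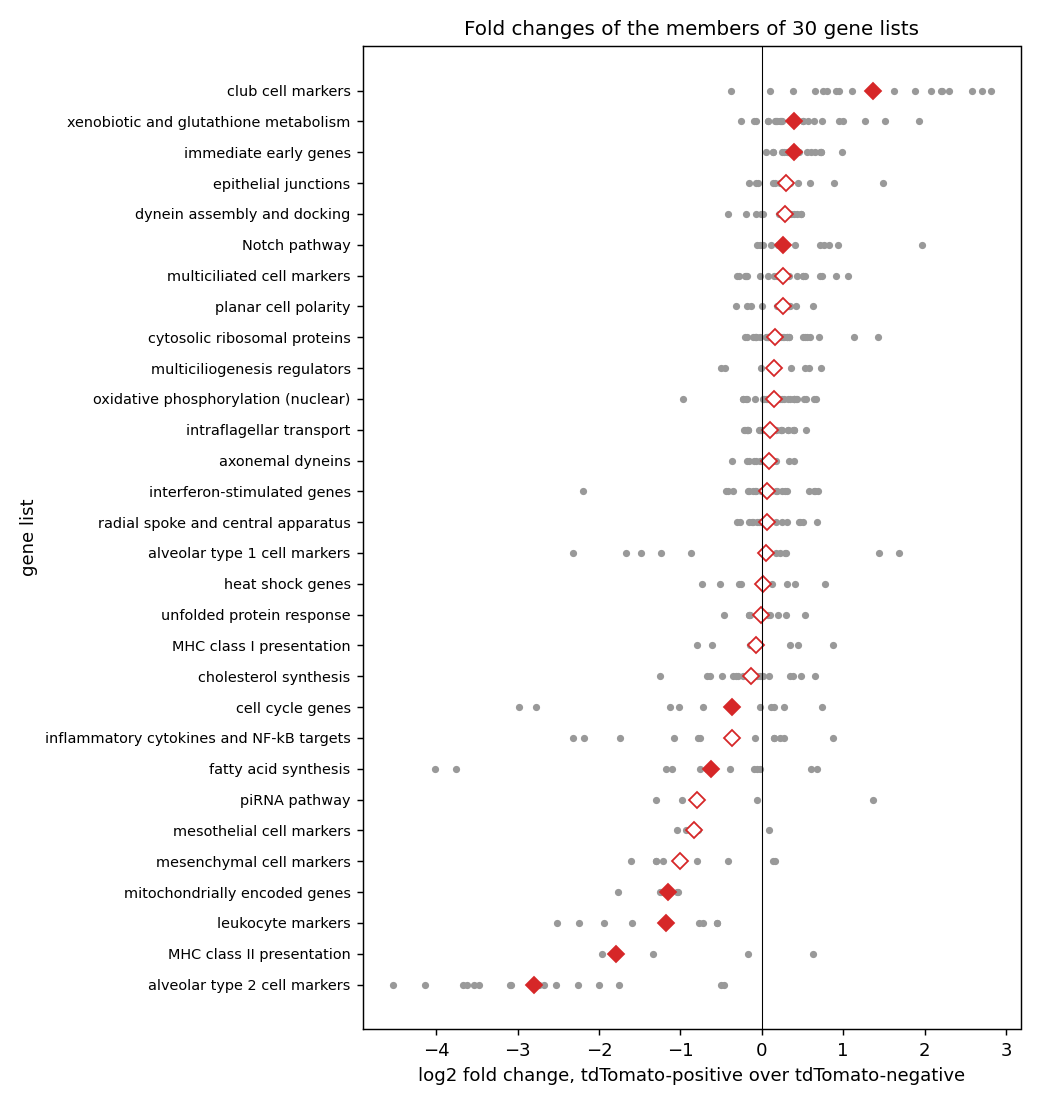
Log2 fold changes (tdTomato-positive over tdTomato-negative, horizontal axis) of the members of the 30 gene lists tested, with a grey point per gene and a diamond at the list median, filled where the camera adjusted p at the preset correlation was under 0.05. The alveolar type 2 list lies lowest, with a median of -2.80, and the club cell list highest, with a median of 1.37.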

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

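The share of reads that overlapped more than 1 gene and were therefore counted for none lies outside the gene counts used above, and it was 1.94% in the tdTomato-positive libraries against 1.44% in the negative ones (means, n = 3 each). Its range was 1.91% to 1.99% in the positive and 1.31% to 1.697% in the negative libraries, so every positive library was above every negative one. The exact permutation p, which leaves the pairing by mouse unused, was 0.1, the smallest that 3 against 3 allows. No explanation for it was tested.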

How the results depend on the processing

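Of the genes taken by the naming rule and the lists, none that was called reversed; 7 of these genes and 12 lists, none of them called, changed sign under at least 1 alternative. The GC and length correction, the run without mitochondrially encoded genes and the blocked fit with an estimated correlation were chosen after seeing the data. Against 82 genes changed, 6 higher and 76 lower, the counts were 413, 167 and 246 with no expression filter, 250, 59 and 191 with DESeq2, and 52, 2 and 50 in the test against a fold of 1.5. With the mouse as a replicate block they were 415, 179 and 236 in edgeR, 464, 224 and 240 in DESeq2, and 303, 153 and 150 with the GC and length correction. With library size only, 22 genes were higher. Leaving out 1 library or 1 mouse gave 22 to 113 genes changed, 2 to 15 higher and 17 to 98 lower. Fewer samples enter these fits, which does not by itself explain counts above 82. The cause was not tested for these or the other settings.

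The Piwil4 log2 fold change was 1.194 to 1.468 without 1 library or mouse, and the test against a fold of 1.5, with the same estimate of 1.365, gave an adjusted p of 0.0713; over all its alternatives adjusted p was 1.59e-08 to 0.165. Against 10 gene lists past the threshold there were 23 with no expression filter, 1 with the correlation estimated, 2 with fry and 0 in the blocked fit with the correlation estimated. The replicate block made 24 of 123 other named genes and 3 of 30 lists pass that had not, and ended the call of 0 of either. RLE normalization changed the call of 0 of these genes and lists. Sftpc, Lpcat1 and Lyz2 were called in all 22 of their alternatives. In simulated data with an assumed mouse effect, the main model recovered 0% of 2-fold changes. In the real libraries it did call some genes near 2-fold. Among them were Pi4k2b (2.03-fold lower, edgeR adjusted p = 0.0312) and Dst (2.12-fold lower, edgeR adjusted p = 0.00693).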

Other observations

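Further genes outside the naming rule were chosen after their values were seen. Among the 76 genes that fell, Lamp3, a lysosomal membrane protein, was 23.1-fold lower (edgeR adjusted p = 0.00575). Lamp3 is on the alveolar type 2 list and was already counted there. Also lower were Dram1, a lysosomal regulator of autophagy (162 against 13.8 CPM; edgeR adjusted p = 0.000174), Mme, the peptidase neprilysin (137 against 14.2 CPM; edgeR adjusted p = 0.000448), Nrp1 (59.8 against 4.10 CPM; edgeR adjusted p = 0.00209) and Cftr, a chloride channel (30.7 against 3.55 CPM; edgeR adjusted p = 0.00623). The secretory genes Scgb1a1, Scgb3a1 and Scgb3a2 are on the club cell list and were already counted in its blocked calls. With the mouse as a replicate block they had log2 fold changes of 2.09, 2.60 and 2.04 (edgeR adjusted p = 1.36e-06, 1.52e-05 and 4.62e-05), against adjusted p of 0.479, 0.579 and 0.603 without it.

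Xist, expressed from the inactive X chromosome, and the Y-linked Ddx3y both had reads in all 6 libraries. Xist had 138, 112 and 107 reads in the negative and 66, 54 and 32 in the positive libraries of mice 1, 2 and 3, and Ddx3y had 371, 353 and 301 against 413, 197 and 265. Xist was not called by the main model (edgeR adjusted p = 0.0979) and was called as lower with the replicate block (0.0108), and without the block by DESeq2 (0.0116), with no expression filter (0.00652) and without the positive library of mouse 1 (0.042). The sex of the animals is not given in the sources used here, and whether each numbered mouse is 1 animal was not tested, so counts of mice here are counts of the labels' numbers.

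The tests that weigh explanations below were chosen after the data were seen, those of GC content and gene length included, except the other splits for the lists and for the blocked model.

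Alveolar type 2 markers were lower in tdTomato-positive libraries. GC content and length do not account for it as a whole: across genes, fold changes correlated with GC at 0.444 (genes are not independent replicates), yet after that trend was removed in the blocked fit the list median was -2.88, against -3.06 before, with 13 members called in both. A lower share of multiciliated cells in the negative sort, filled by all other epithelial types alike, would raise club cell markers there. The club cell median was instead 1.24 in the positive direction, with 17 of 18 members above 0. Other cell type lists went both ways. Blocked medians were -1.08 for leukocyte, -1.02 for mesenchymal, -0.76 for mesothelial and -0.01 for alveolar type 1 markers. Of the lists too small to test, basal, neuroendocrine, tuft and erythroid medians were below 0 in that fit. The endothelial median was 0 and the goblet median 1.25. A lower share filled by alveolar type 2 cells alone, or by a mix with few club cells, is not tested by the club cell values and stays open. Alveolar type 2 cells or their RNA in the negative sort, which a gate on EpCAM would not remove, stay open: markers from 1 cell type would keep their ratios between negative libraries as well as other genes of like level, and the SD over members was 0.95 times that of those genes on average, yet above it in 2 of 3 pairs (0.62 against 0.45 for mice 1 and 2, 0.48 against 0.47 for mice 1 and 3, 0.26 against 0.52 for mice 2 and 3). A difference between the cell populations that the reporter separates stays open beside it.

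Club cell markers were higher in tdTomato-positive libraries. Dilution by alveolar RNA in the negative libraries would raise ciliary genes by the same factor. The blocked axonemal dynein median was 0.07 and all 16 members lay below 0.62, the bound set at 0.5 of the club cell median. These dynein values were not corrected for GC and length, but the list median was at most 0.346 over all its alternatives, that correction included. The blocked median of multiciliated cell markers was 0.26. Some of those markers lay above the bound in that fit, among them Foxj1 (1.20), Tppp3 (1.02), Tekt4 (0.718) and Cfap126 (0.697). Removing the GC and length trend left a median of 1.16, with 6 members called in place of 8, but the members' middle range reached down to 0.56, so a contribution of that trend stays open. Club cells or their RNA in the positive sort cannot be told apart from expression in the sorted cells, since the members' own level in multiciliated cells was not measured. The SD over members of the log2 difference within a mouse was 1.07 as the mean of the mice.

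Mitochondrially encoded mRNAs were lower in tdTomato-positive libraries. After the GC and length correction in the blocked fit the median was -0.86, against -1.29 before, and all 7 members were still called, so that trend may account for part of the size and not the whole. Fewer mitochondria with their nuclear-encoded proteins would lower the nuclear oxidative phosphorylation genes, whose blocked median was 0.11, with 29 of 30 above the bound of -0.64. A lower amount of all mitochondrial RNA stays open: the ribosomal RNAs mt-Rnr1 and mt-Rnr2 were lower in the positive library in 5 of 6 comparisons within mice, the exception being mt-Rnr1 in mouse 1.

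The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixes positive and negative libraries in both groups. The difference between the fractions then adds to the spread within groups, so low gene counts in those splits do not measure chance. The real split gave 82 genes, as the 1 split with that many, and the highest other gave 1. With the mouse as a block, 4 splits part all mice; the real one gave 415 genes, the 1 split with that many, and the highest other gave 1. For the gene lists the real split gave 10, and 4 of the 10 splits, the real one included, gave as many; the highest other gave 13. The other splits with as many, at 11, 13 and 13 lists, part only 1 of the mice, and so compare mice in part. Among the 4 splits that part all 3 mice the real one gave 10 lists and the highest other 5.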
